A study of Mus musculus with 16 samples.

How the data were processed

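The series measured RNA in the hippocampus of 2-month-old male mice of 4 genotypes with 16 Affymetrix mouse expression arrays, 4 per genotype. Labelled cRNA was made from total RNA extracted with Trizol, per the labels' protocols. The groups are called here by the names the sample titles carry: WT, APP_KO, APLP2_KO and N_dCKO. The series title describes the double knockout as neuronal and conditional, while the genotype label of N_dCKO gives both genes as lost; which cells carried the deletion is not stated in the sources used here. The titles number the replicates 1 to 4 in each group, and nothing in the labels says outright that they are separate animals, so the p-values measure the spread between these samples, which may be technical.

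The deposited values are intensity values on a linear scale, made by the authors with MAS5, per the submitters' processing notes; its version is not given in the sources used here. The deposited intensity of every array had a 2% trimmed mean of 500, and no value was at or below 0. This global scaling by the authors was kept, and no further normalization was applied. The table held 45101 probe sets, of which 64 were control probe sets. Of all probe sets, 34945 were paired with 1 gene symbol, 932 with several and 9211 were not listed in the annotation table used; probe sets with several symbols or none were not given a gene name. Symbols were looked up by gene number in a table of the GRCm38.p6 assembly, which held 34741 of the probe sets with 1 symbol and changed 0 symbols. That table was used only for names and for which genes lie near each other, since the array values come with no genome build.

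Signals were transformed as log2(signal + 9), with a pseudocount of 9 set from the median signal of 91.7 over all values. A fold change on this scale understates the change of dim genes. Probe sets at or above the median of mean log2 signal (6.60, a signal of 88) were kept, which left 22551. For each gene the probe set with the highest mean was used, giving 11664 genes. The model was fitted with limma 3.58.1 in R 4.3.3, and the values were read with the R package data.table, version 1.17.8. It had 1 mean per group over all 16 arrays and moderated variances that follow a trend with intensity. It had 12 residual degrees of freedom and 19.4 in the moderated test. Two-sided p-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene is called changed at an adjusted p below 0.05. Values after ± are SE for log2 fold changes and SD for signals and ratios, with n = 4 per group. The number of arrays limits the precision. The median SE of a log2 fold change was 0.098 in the comparisons of 2 groups and 0.138 in the interaction.

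The comparisons were each single knockout against WT, N_dCKO against WT and against each single knockout, and the interaction of both losses. App, Aplp2 and Aplp1 were also tested probe set by probe set with an exact two-sided permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286. Of 39 lists of cell type markers and pathway genes, 37 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01. Their p-values were adjusted over the 37 lists of each comparison. The variance trend with intensity was used in camera as in the fit. The plan had left this open, and the trend was chosen after camera without it had been run on these data. Values without it are therefore given for the calls that held with an estimated correlation. The calls lost without it at the preset correlation are named further below. Beside it stand camera with an estimated correlation, fry, and counts of members after adjustment over the list alone. Overlap of comparisons that share the WT arrays was set against 100 simulations of unchanged groups. Fisher's exact test compared the share of called genes within 10 Mb of App and of Aplp2 with the share elsewhere.

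Named genes follow a rule: App, Aplp2 and Aplp1; in each comparison up to 10 called genes with the largest rise and up to 10 with the largest fall whose 4 arrays of one group all lie above the 4 of the other; genes called in the same direction in all 3 knockout groups against WT; where no gene passed, the 5 with the smallest unadjusted p, as values only; and 2 to 4 members with the smallest p of each list with a call or a called member. Genes withheld for evaluations are left out. Groups, comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined; alternatives and genes chosen later are named as such. The alternatives were quantile normalization, median centring, other pseudocounts and filters, the mean over probe sets, each probe set alone, no variance trend, array weights, the replicate number as a block, only the groups compared, an ordinary test without moderated variances, other window sizes, a split of the WT arrays, and leaving out each array. Added after seeing the data were the choroid plexus score as a covariate, the log2 ratio of 3' to 5' Gapdh signal as a covariate, a test without genes that follow that score, the block within the groups compared, camera without the variance trend, and main effects over 8 against 8 arrays.

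Same-numbered arrays were checked for pairing by the correlation of their deviations from the group means. WT and APP_KO arrays of the same number correlated at 0.30, 0.29, 0.20 and 0.19, all above 0.1, so these numbers pair the samples as far as the data show; no other pair of groups passed in all 4. With the number as a block, APP_KO against WT still had 1 called gene and 11 called lists. No pair of arrays was identical, and the highest correlation between 2 arrays was 0.992. The fit was tested on simulated data for N_dCKO against WT with 11664 genes over 20 simulations: 68.7% of genes changed by a log2 of 0.5 and 95.7% of those changed by 1 were recovered, and 4.80% of the calls were false. A list shifted by -0.30 was called in 20 of 20 simulations, and 0 of 740 unchanged lists were called. The genes were simulated independently of each other, so this does not measure false calls among lists whose members vary together.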

Results

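RNA from the hippocampus of 2-month-old male mice was measured on 16 Affymetrix arrays, 4 each from WT mice, mice without APP (APP_KO), mice without APLP2 (APLP2_KO) and mice of the neuronal double conditional knockout (N_dCKO). APP is the amyloid precursor protein, and APLP2 and APLP1 are its relatives. The median signal ranged from 79.7 to 102 and the mean correlation of an array with its own group from 0.986 to 0.990. The ratio of 3' to 5' Gapdh signal, a measure of RNA quality, was 0.76 ± 0.02 in WT (SD, n = 4), 0.78 ± 0.03 in APP_KO and in APLP2_KO, and 0.81 ± 0.02 in N_dCKO. All N_dCKO arrays (0.797 to 0.834) lay above all WT arrays (0.752 to 0.786), with an exact two-sided permutation p of 0.0286, adjusted 0.286 over 10 tests. The same ratio of actin had group means between 1.60 and 1.67. WT was at 1.64 and N_dCKO at 1.63. The labels do not state that the 4 samples of a group are separate animals, so p-values reflect the spread between these samples, which may be technical.

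App and Aplp2 signals were low in the groups labelled as lacking them and in no other group. The App probe set with the highest signal read 18500 ± 1100 in WT (SD, n = 4), 2511 ± 180 in APP_KO, 19650 ± 1410 in APLP2_KO and 2191 ± 195 in N_dCKO, so that APP_KO kept 13.6% and N_dCKO 11.8% of the WT signal. Another App probe set kept 5.76% and 5.34%, and the remaining pair of App probe sets lay near background in every group and checks nothing. Where the probes lie relative to the deleted part of the gene is not given in the sources used here. Aplp2 read 5984 ± 229 in WT, 5778 ± 277 in APP_KO, 1162 ± 276 in APLP2_KO and 998.5 ± 122 in N_dCKO, or 19.4% and 16.7% of WT in the groups without it. The other 4 Aplp2 probe sets gave log2 fold changes of -1.25, -2.07, -3.17 and -3.46 in APLP2_KO against WT. All of these falls had an exact permutation p of 0.0286 (two-sided, 4 against 4 arrays), the smallest this design allows. Aplp1 had log2 fold changes of 0.04 in APP_KO, 0.04 in APLP2_KO and -0.04 in N_dCKO against WT, each ± 0.07, with exact permutation p of 0.571, 0.657 and 0.629.

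**Figure D1:**
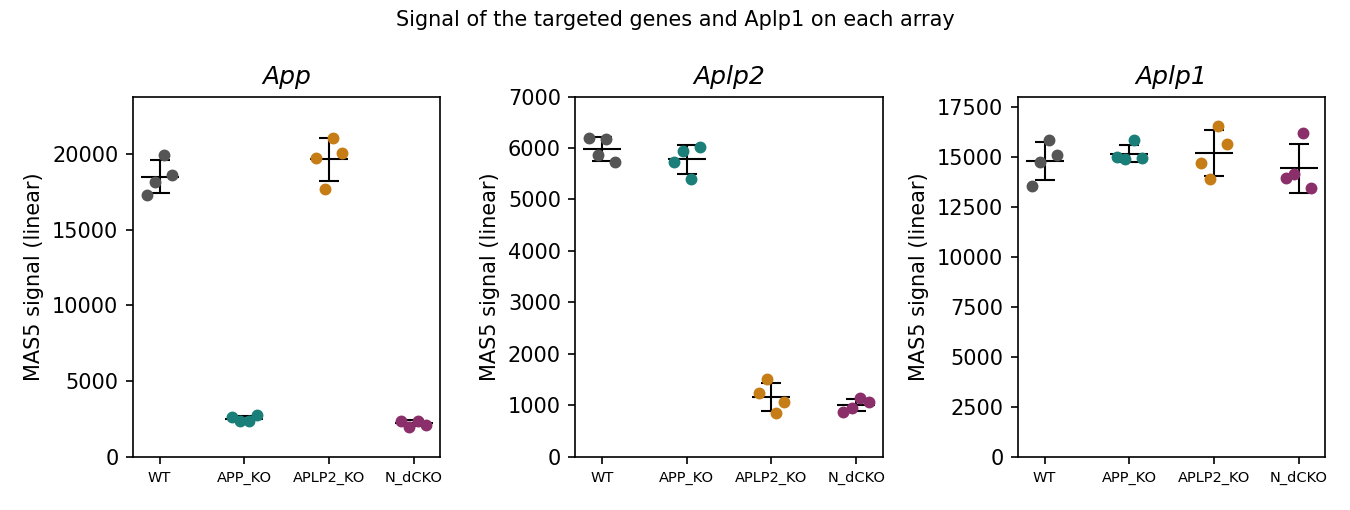
Linear MAS5 signal of the representative probe sets of App, Aplp2 and Aplp1 on each array, 1 point per array, with the mean ± SD of the 4 arrays per group. App falls from 18500 in WT to 2511 in APP_KO and 2191 in N_dCKO, and Aplp2 from 5984 to 1162 in APLP2_KO and 998.5 in N_dCKO, while Aplp1 stays between 14453 and 15214 in the group means.

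The first comparison asked what the loss of APP alone changes. App was the 1 gene of 11664 called, with a log2 fold change of -2.88 ± 0.07 (limma adjusted p = 2.56e-16). No other gene passed, and 604 genes had an unadjusted p below 0.05, where chance gives 583. The 4 arrays of each group did not overlap for 2.63% of all tested genes, where chance gives 2.86%. As groups, genes of oligodendrocytes and myelin, microglia, and cholesterol and fatty acid synthesis lay lower in APP_KO. Of 16 genes of oligodendrocytes and myelin, which insulates axons, 15 had negative log2 fold changes with a median of -0.40, among them Mag (-0.52 ± 0.12), Cldn11 (-0.52), Mog (-0.64) and Gsn (-0.56). None passed over all genes, and 9 were lower when adjusted over the list alone. All 16 microglia genes were negative, with a median of -0.14 and 3 lower when adjusted over the list alone, such as C1qb, a part of complement C1q (-0.28 ± 0.07), and Tyrobp, a signalling adaptor of microglia (-0.31 ± 0.08). Of 19 genes of cholesterol and fatty acid synthesis, 17 were negative, with a median of -0.17 and 4 lower over the list alone, such as Fdft1 (-0.25) and Idi1 (-0.40). The camera test called these lists at adjusted p of 3.67e-14, 6.82e-08 and 7.84e-09, and none of the calls held with an estimated correlation (adjusted p = 0.206, 0.0538 and 0.116). With only the WT and APP_KO arrays and the replicate number as a block, a fit chosen after seeing the data, 6 genes were called. Without APP_KO array 2, 16 genes were called, all lower and 6 of them on the myelin list: Cldn11 -0.66, Gsn -0.76, Mag -0.67, Mal -0.85, Mog -0.85 and Opalin -0.70. No other fit without 1 array called as many, and the array left out goes against the pattern. Its mean log2 signal of the myelin list was 11.81, within the 11.53 to 11.95 of WT, while the other APP_KO arrays read 11.06 to 11.29.

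A further 8 lists were called in APP_KO against WT with smaller shifts, and none held with an estimated correlation. Genes of dentate granule neurons lay lower (median -0.06, adjusted p = 0.395 with an estimated correlation). Higher were immediate early genes (0.11, 0.627), glutamate receptors (0.06, 0.274), insulin and IGF signalling (0.06, 0.206), oxidative phosphorylation (0.02, 0.636), neurogenesis and proliferation (0.09, 0.554), neuropeptides (0.08, 0.274) and ribosomal proteins (0.05, 0.627), each given as the median log2 fold change and that adjusted p. Of 19 neuropeptide genes, Vgf (0.26) and Hcrt (0.64) were higher when adjusted over the list alone, and 0 passed over all genes. Apart from insulin and IGF signalling, which was lost without a filter (0.0559), each of these calls was lost without 1 or more of WT arrays 1, 2 and 3 and APP_KO arrays 1, 2, 3 and 4, with adjusted p up to 0.917 for immediate early genes without APP_KO array 2.

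The comparison of APLP2_KO with WT asked the same of APLP2. It called 15 genes, 7 higher and 8 lower, against 868 at an unadjusted p below 0.05. Over all tested genes, the 4 arrays of each group did not overlap for 4.40%, where chance gives 2.86%. Besides Aplp2 (-2.39 ± 0.12, limma adjusted p = 1.87e-10), the calls that held whichever array was left out were of 7 genes. Fxyd2, a regulatory subunit of the sodium pump, rose by 1.12 ± 0.17 on the log2 scale (adjusted p = 0.00497), 2900052N01Rik by 1.02 ± 0.16 (0.00585), Galc, a lysosomal enzyme that breaks down myelin lipids, by 0.86 ± 0.10 (0.00014), and Trub2, a pseudouridine synthase, by 0.66 ± 0.10 (0.00619). Pdgfd, a growth factor of the PDGF family, fell by 1.46 ± 0.23 (adjusted p = 0.00619), Mpeg1, a pore-forming protein of macrophages and microglia, by 1.12 ± 0.14 (0.000439), and Ddx6, an RNA helicase, by 0.61 ± 0.08 (0.0011). The other 7 calls were lost in 4 to 7 of the 8 fits that left out 1 array, with adjusted p up to 0.147 for Klf10 and Rpp25 without WT array 3: Uggt2 (0.85), Klf10 (0.49) and Ift46 (0.45) higher, and Htr3a (-1.03), Zfp874a (-0.87), Coro2b (-0.68) and Rpp25 (-0.66) lower. The calls of Ddx6 in APLP2_KO against WT (-0.02) and Coro2b in APLP2_KO against WT (-0.37) were lost with the mean over probe sets. The count fell to 9 without WT array 1, 2 or 3 and to 3 with the 75th percentile filter, and rose to 30 with the replicate block. It was 8 with the Gapdh ratio as a covariate, chosen after seeing the data. An ordinary equal-variance test per gene called 0, Aplp2 among those missed. Of the 15 genes, 9 lie on chromosome 9, which carries Aplp2, namely Aplp2, Fxyd2, 2900052N01Rik, Pdgfd, Ddx6, Htr3a, Coro2b, Rpp25 and Ift46.

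Microglia genes were lower in APLP2_KO too: 15 of 16 were negative with a median of -0.21, 6 were lower when adjusted over the list alone, and 0 passed over all genes. Examples are Fcrls (-0.66 ± 0.15), Tyrobp (-0.34 ± 0.08), C1qc (-0.25) and Ctss (-0.40). The camera test gave an adjusted p of 1.94e-08, and this was the 1 list of this comparison called with an estimated correlation (adjusted p = 0.0334, and 0.0346 without the variance trend). Of 19 genes of ER stress and heat shock, 16 were negative, with a median of -0.19 and 5 lower over the list alone, such as Hspa5, an ER chaperone (-0.40 ± 0.10), Manf (-0.38), Sdf2l1 (-0.53) and Herpud1 (-0.30), at adjusted p = 4.51e-06, or 0.393 with an estimated correlation. All 8 genes of oligodendrocyte precursors were positive (median 0.16, adjusted p = 0.00118, or 0.163 with an estimated correlation). Of 18 choroid plexus genes, 15 were negative (median -0.46, adjusted p = 0.0237), and the call was lost with an estimated correlation (adjusted p = 0.685) and without WT array 1 (0.141), WT array 2 (0.455) or APLP2_KO array 4 (0.121). The other 5 lists were higher, none with an estimated correlation: astrocytes (median 0.07, adjusted p = 0.0983 with an estimated correlation), leptomeninges and fibroblasts (0.17, 0.515), presynaptic vesicle cycle (0.06, 0.419), neurogenesis and proliferation (0.14, 0.419) and neuropeptides (0.11, 0.258). They were each lost without 1 or 2 of WT arrays 1, 2 and 3 and APLP2_KO arrays 3 and 4, with adjusted p up to 0.586 for leptomeninges and fibroblasts without APLP2_KO array 4.

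N_dCKO against WT asked what the loss of both genes changes. It called 110 genes, 29 higher and 81 lower, with 1397 at an unadjusted p below 0.05, and the arrays did not overlap for 7.36% of all tested genes, where chance gives 2.86%. The falls of the largest size, App and Aplp2 aside, were mostly in genes of the choroid plexus, the tissue in the ventricles that makes cerebrospinal fluid. Of 18 choroid plexus genes, 15 fell, and 16 were lower when adjusted over the list alone, with a median log2 fold change of -1.96. Clic6, a chloride channel protein, fell by 3.71 ± 0.55 (limma adjusted p = 0.00196), Kcnj13, a potassium channel, fell by 2.81 ± 0.42 (0.00196), Kl, which encodes klotho, fell by 2.12 ± 0.31 (0.0019), and Cldn2, a tight junction protein, fell by 2.02 ± 0.30 (0.00196). Kcne2 (-3.49), Otx2 (-3.24), Folr1 (-2.86) and Aqp1 (-2.44) of the same list fell too, as did Defb11 (-3.55 ± 0.44), Ecrg4 (-3.39) and Prr32 (-2.84) outside it, with adjusted p between 0.000484 and 0.00426. On N_dCKO arrays 1, 2 and 4 signals reached the level of background, such as 4.99, 4.87 and 10.8 for Kcne2, 0.425, 8.38 and 14.4 for Otx2 and 33.6, 9.16 and 7.53 for Defb11. Their log2 fold changes are therefore no exact sizes and depend on the pseudocount. With 4 times the pseudocount they were -2.47, -2.23 and -2.71, and with none -4.43, -4.76 and -4.16. The calls of the choroid plexus genes named so far, and of Defb11, Ecrg4 and Prr32, held whichever array was left out. All of them were lost in the ordinary test without moderated variances. Ttr, the transthyretin gene, was lower too (adjusted p = 0.0204), a call that was lost in 5 of 8 fits with 1 array left out, with an adjusted p of 0.0754 without N_dCKO array 1.

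The N_dCKO arrays were not alike in this. The mean log2 signal of the choroid plexus list was 6.42, 6.80, 8.65 and 6.81 on N_dCKO arrays 1 to 4, against 8.46 to 9.75 on the other 12 arrays, so that array 3 lay within the range of the other groups. Ttr read 110, 283, 34285 and 715 on these arrays and 26344 to 37234 on the other 12, where the highest signals of any probe set were 29153 to 38601. Its probe set thus lay near the ceiling of the array, and no fold change is given for it. The list was called by camera at an adjusted p of 2.14e-31, at 0.0411 with an estimated correlation and at 0.0729 when the variance trend was left out as well. With the mean of the choroid plexus list as a covariate, 3 genes were called and the values of Kcne2 and Otx2 turned to 0.08 and 0.13. Without the 52 genes that followed the list in the other 12 arrays 63 were called. Both alternatives were chosen after seeing the data. Of the 110 calls, 23 were among those 52 genes, so the count fell by more than the calls taken out. The count of 110 was 170 with array weights and 198 with the replicate block. It was 64 without WT array 1, 45 without WT array 2, 46 without N_dCKO array 1 and 65 without N_dCKO array 2, and an ordinary equal-variance test per gene called 5. With the Gapdh ratio as a covariate, also chosen after seeing the data, 23 were called. The calls of Kcne2 (adjusted p = 0.0676), Otx2 (0.0698), Cldn2 (0.0654) and Prr32 (0.117) were then lost at log2 fold changes of -3.74, -3.49, -1.92 and -2.71. Genes of the ependyma, which lines the ventricles, were all 10 negative (median -0.40, adjusted p = 0.000221, or 0.132 with an estimated correlation), such as Foxj1 (-0.84) and Ccdc153 (-1.23).

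**Figure D2:**
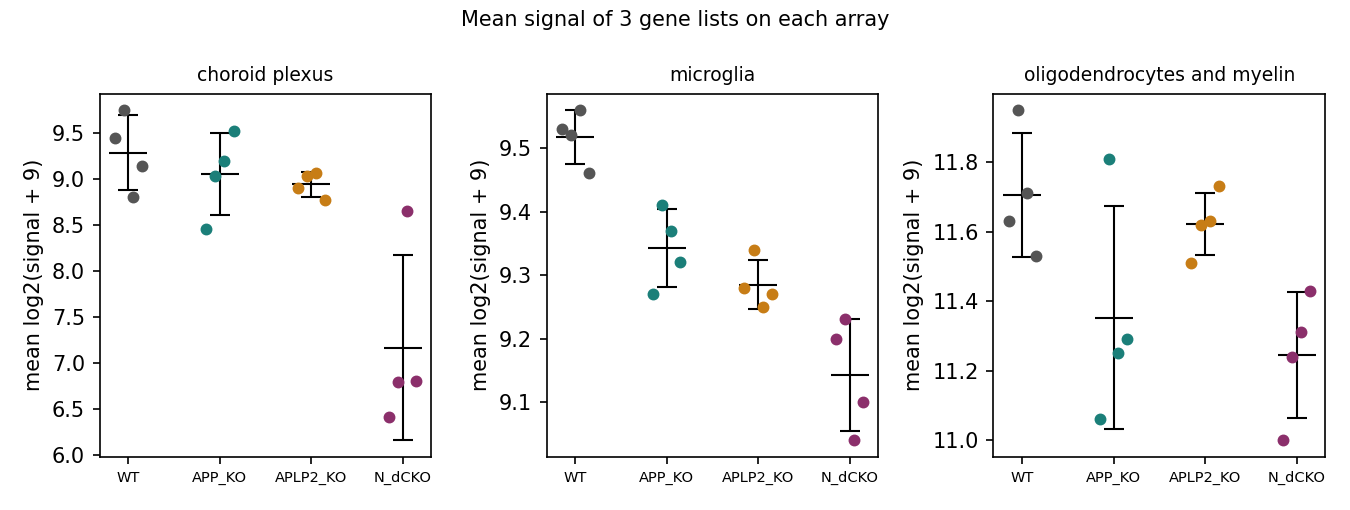
Mean log2(signal + 9) of the genes of 3 lists (choroid plexus, microglia, oligodendrocytes and myelin) on each array, 1 point per array, with the mean ± SD of the 4 arrays per group. The choroid plexus mean is 6.42, 6.80 and 6.81 on 3 N_dCKO arrays and 8.65 on the remaining one, while the microglia mean is 9.52 ± 0.04 in WT and 9.14 ± 0.09 in N_dCKO.

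Microglia genes were the list that held under every setting tried for N_dCKO against WT. Of 16 genes, 6 fell, 11 were lower when adjusted over the list alone, and all 16 were negative with a median of -0.39. Fcrls fell by 0.86 ± 0.15 (limma adjusted p = 0.00539), and the 3 subunits of complement C1q fell together, C1qa by 0.46 ± 0.07 (0.0025), C1qc by 0.42 (0.00318) and C1qb by 0.41 (0.00368). The call of C1qb in N_dCKO against WT was lost with the mean over probe sets (-0.29), and that of C1qc with only these groups in the fit and the replicate number as a block. The camera test of the microglia list gave 1.09e-16, with 0.00201 at an estimated correlation, 0.00207 without the variance trend as well 3.73e-11 with the choroid plexus mean as a covariate and 1.7e-12 with the Gapdh ratio as one. The 4 named genes lost the call with either covariate; standard errors were larger with both, and the Gapdh ratio also gave smaller falls. With the choroid plexus mean Fcrls was at -1.22 ± 0.26 (limma adjusted p = 0.121), C1qa at -0.58 ± 0.13 (0.126), C1qb at -0.54 ± 0.12 (0.133) and C1qc at -0.42 ± 0.13 (0.456). With the Gapdh ratio they were at -0.69 ± 0.19 (0.229), -0.34 ± 0.09 (0.185), -0.34 ± 0.09 (0.19) and -0.41 ± 0.09 (0.105). The mean log2 signal of the list was 9.52 ± 0.04 in WT, 9.34 ± 0.06 in APP_KO, 9.29 ± 0.04 in APLP2_KO and 9.14 ± 0.09 in N_dCKO (SD, n = 4). Of 13 interferon response genes, Ifi27 fell by 0.68 ± 0.11 (adjusted p = 0.00229) and 12 were negative, at 0.000432 by camera, or 0.125 with an estimated correlation. The Ifi27 call was lost with the choroid plexus covariate (-0.59 ± 0.19, 0.523) and with the Gapdh ratio (-0.61 ± 0.14, 0.105).

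Of 16 genes of oligodendrocytes and myelin, all were negative in N_dCKO against WT with a median of -0.47. Mal, a myelin membrane protein, was called (-0.90 ± 0.20, limma adjusted p = 0.0309), and 14 were lower when adjusted over the list alone, such as Mag (-0.50), Opalin (-0.66) and Gsn (-0.61). The list had a camera adjusted p of 1.54e-13, or 0.092 with an estimated correlation. Of 19 genes of cholesterol and fatty acid synthesis, Fdps (-0.38) and Sc5d (-0.39) fell and 17 were negative (median -0.17, adjusted p = 0.000153, or 0.125 with an estimated correlation). The list call was also lost with the Gapdh ratio as a covariate. Sc5d lies on chromosome 9 within 20 Mb of Aplp2, and its call was lost with the mean over probe sets. The calls of Mal, Fdps and Sc5d were lost in 5 to 7 of 8 fits with 1 array left out, with adjusted p up to 0.134 for Fdps without WT array 2. Of 19 genes of ER stress and heat shock, 17 were negative and 1 was lower over the list alone (median -0.25, adjusted p = 0.000105, or 0.184 with an estimated correlation). Genes of dentate granule neurons were lower as a list (median -0.13, adjusted p = 0.0036, or 0.125 with an estimated correlation), with Tdo2 at -0.38 and C1ql2 at -0.31. The list of the APP family and processing was lower (adjusted p = 0.031, or 0.092 with an estimated correlation, 0.0543 without WT array 4 and 0.0851 without N_dCKO array 4), and App and Aplp2 were its 2 called genes. Both are the genes that this group is labelled as lacking. Their own falls enter the list test, so its call shows no change of the other members.

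Several lists of neuronal genes were higher in N_dCKO than in WT. Reln, a secreted protein of hippocampal interneurons, rose by 0.43 ± 0.09 (limma adjusted p = 0.0206), and 13 of the 14 genes of GABAergic interneurons had positive values, with Htr3a at -0.62 as the exception and 3 higher and 1 lower when adjusted over the list alone. That list had a median of 0.16 and an adjusted p of 0.000105, which was 0.0384 with an estimated correlation, 0.0576 without the variance trend as well and 0.127 with the choroid plexus mean as a covariate, which is confounded with the group. Genes of astrocytes had a median of 0.10 (adjusted p = 0.00261), with 0.0411 at an estimated correlation, 0.0729 without the variance trend as well and 0.0909 with that covariate. Choroid plexus genes were low on 3 of the same 4 N_dCKO arrays. Vgf (0.30) and Crh (0.68), both of the neuropeptides list, were called. Among the other genes called higher were Fxyd2 (1.03), 2900052N01Rik (1.11) and Trub2 (0.55), which held whichever array was left out, and Filip1 (0.78), Cntrob (0.61), Lrrc49 (0.49), Zbtb16 (0.47), Col19a1 (0.46) and Tenm3 (0.45). Of these genes, Fxyd2, 2900052N01Rik, Filip1, Lrrc49 and Zbtb16 lie on chromosome 9, which carries Aplp2. Fxyd2 and Trub2 lost the call with the Gapdh ratio as a covariate (1.09 ± 0.23, adjusted p = 0.0638, and 0.57 ± 0.14, 0.154). The 6 from Filip1 to Tenm3, Reln, Vgf, Crh and the lower Cd82 (-0.80) and Ppp1r1b (-0.66) were lost in 3 to 7 of 8 fits with 1 array left out, with adjusted p up to 0.166 for Crh and Filip1 without N_dCKO array 1.

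Several further neuronal lists were higher in N_dCKO against WT by camera and not with an estimated correlation, here given as the median log2 fold change and the adjusted p with that correlation. They were CA1 pyramidal neurons (0.13, 0.0534), immediate early genes (0.16, 0.246), glutamate receptors (0.14, 0.0534), presynaptic vesicle cycle (0.06, 0.167), GABA receptors (0.11, 0.092), calcium channels, stores and pumps (0.09, 0.125), sodium and potassium channels (0.09, 0.092), adhesion and axon guidance (0.11, 0.125), neurogenesis and proliferation (0.12, 0.153), circadian clock (0.08, 0.352) and neuropeptides (0.11, 0.0595). Their members include Grin2b (0.33 ± 0.11), a subunit of the NMDA receptor, Egr2 (0.83 ± 0.30), an immediate early gene, and Pou3f1 (0.23), none of which passed over all genes. The GABA receptors call was lost without N_dCKO array 1 (0.0841), and that of the circadian clock without WT array 3 (0.161), WT array 4 (0.161), N_dCKO array 3 (0.0841) or N_dCKO array 4 (0.135). With the Gapdh ratio as a covariate, GABA receptors, the circadian clock, and calcium channels, stores and pumps lost the call. The circadian clock lost it without a filter too.

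**Figure D3:**
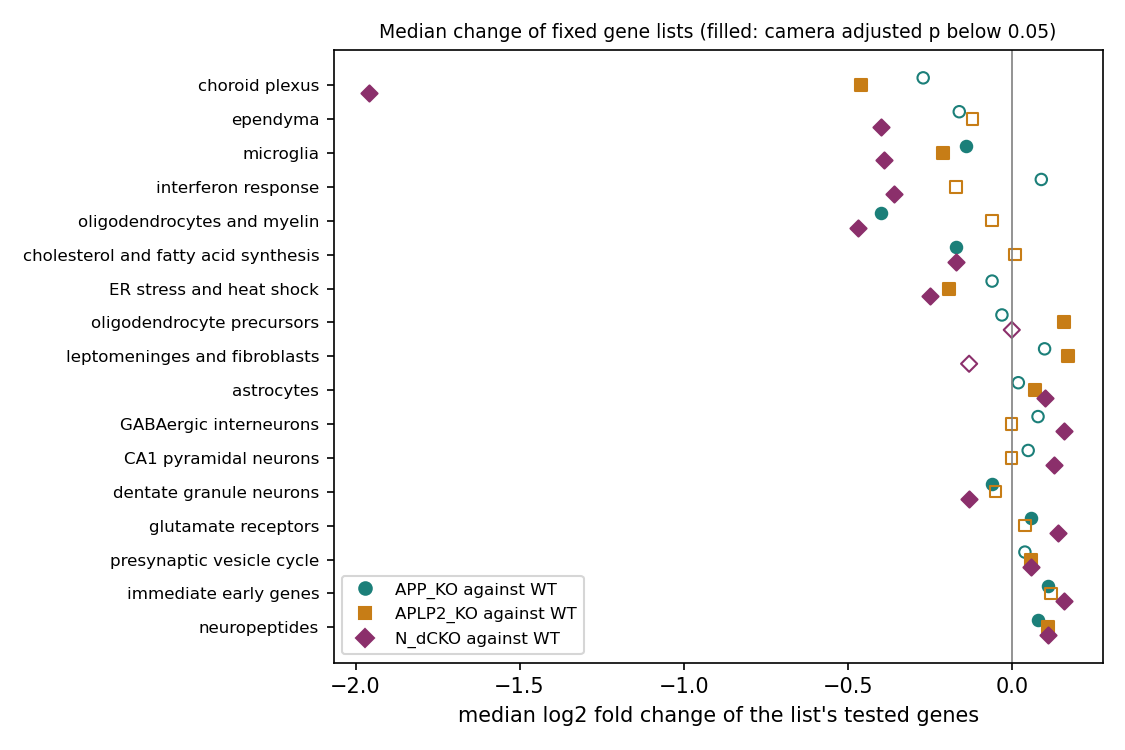
Median log2 fold change against WT of the genes of 17 lists in APP_KO, APLP2_KO and N_dCKO, with filled points for lists with a camera adjusted p below 0.05. The choroid plexus median is -1.96 in N_dCKO and -0.46 in APLP2_KO, and the microglia medians are -0.14, -0.21 and -0.39 in APP_KO, APLP2_KO and N_dCKO.

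N_dCKO against APLP2_KO asks what the loss of APP adds where APLP2 is already missing. App (-3.16 ± 0.07, limma adjusted p = 4.18e-17), Defb11 (-2.69 ± 0.44, 0.0314) and Cldn2 (-1.80 ± 0.30, 0.0314) fell, and 985 genes had an unadjusted p below 0.05. The arrays did not overlap for 5.23% of all tested genes, where chance gives 2.86%. The calls of Defb11 and Cldn2 were lost in 7 of 8 fits with 1 array left out, with adjusted p of 0.163 and 0.188 without APLP2_KO array 3. The count was 1 without any APLP2_KO array or N_dCKO array 1, 2 or 4 and with the Gapdh ratio as a covariate. It was 35 without N_dCKO array 3, 30 with array weights and 17 with the replicate block. All 18 choroid plexus genes were negative (median -1.63, adjusted p = 2.91e-33, or 0.0611 with an estimated correlation), and 16 were lower over the list alone. Genes of GABAergic interneurons were the 1 list called with an estimated correlation: 7 of 14 were higher over the list alone, such as Slc32a1, the vesicular GABA transporter (0.28 ± 0.08), Kcnc1 (0.38) and Pvalb (0.26), with a median of 0.18 and an adjusted p of 1.76e-06, which was 0.0196 with an estimated correlation and 0.0297 without the variance trend as well. Lower were oligodendrocytes and myelin (median -0.37, adjusted p = 0.102 with an estimated correlation), microglia (-0.18, 0.0779), cholesterol and fatty acid synthesis (-0.17, 0.0779) and leptomeninges and fibroblasts (-0.34, 0.136), with 11, 3, 2 and 2 members lower over the list alone. Their members with the smallest p were Mag (-0.53), C1qa (-0.24), and Dcn, a proteoglycan of connective tissue (-0.48 ± 0.08, limma adjusted p = 0.0566). The other 12 called lists had medians within 0.26 of 0, and none held with an estimated correlation (adjusted p between 0.0928 and 0.516). Of these, 7 were lost without 1 or more of APLP2_KO arrays 1, 2 and 4 and N_dCKO arrays 1, 2, 3 and 4, with adjusted p up to 0.221 for immediate early genes without N_dCKO array 4.

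N_dCKO against APP_KO asks what the loss of APLP2 adds where APP is missing. It called 41 genes, 7 higher and 34 lower, with 899 at an unadjusted p below 0.05, and the arrays did not overlap for 3.99% of all tested genes, where chance gives 2.86%. Wdfy1 rose by 1.45 ± 0.25 (limma adjusted p = 0.00878, with WT arrays at 0.71, -0.79, -0.58 and 0.65 around their mean), Card10 by 1.16 ± 0.19 (0.00764), Fxyd2 by 1.02 ± 0.17 (0.00772), 2900052N01Rik by 1.02 ± 0.16 (0.00627) and Neo1, a receptor of axon guidance, by 0.43 ± 0.07 (0.00627). Aplp2 fell by 2.53 ± 0.12 (6.28e-11), Pdgfd by 1.59 ± 0.23 (0.00627) and Cetn4 by 1.29 ± 0.22 (0.00878). Of 18 choroid plexus genes, 11 fell and 18 were lower over the list alone (median -1.69, adjusted p = 3.71e-36), including Clic6 (-3.33), Aqp1 (-2.37) and Folr1 (-2.59); Defb11 (-2.83) fell as well. These calls held whichever array was left out, while those of Ttr, Otx2 (-2.96), Prr32 (-2.48), Kl (-1.71), Cldn2 (-1.74), Krt8 (-1.64), Krt18 (-1.09), Fcrls (-0.72), Ifi27 (-0.51), C1qa (-0.38), Trub2 (0.53) and Slc6a15 (0.32) were lost in 1 to 7 of 8 fits, with adjusted p up to 0.18 for Fcrls without APP_KO array 3. With only these groups in the fit, 9 genes were called, and the calls of Aqp1, Cetn4, Clic6, Defb11, Folr1, Neo1 and Pdgfd were among those lost. The count was 22 without APP_KO array 3, 19 without APP_KO array 4 and 20 without N_dCKO array 4. It was 20 with the Gapdh ratio as a covariate too, and the calls of Wdfy1 and Cetn4 were among those lost.

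All 16 microglia genes were negative in N_dCKO against APP_KO, 2 fell and 6 were lower over the list alone (median -0.13, adjusted p = 4.99e-07), with 0.0458 at an estimated correlation and 0.0692 without the variance trend as well. The choroid plexus list had 0.0458 and 0.0854 in the same tests. Of 13 interferon response genes, 12 were negative (median -0.31), and 6 were lower over the list alone, such as Rsad2 (-0.83) and Bst2 (-0.55), at adjusted p = 2.02e-05, or 0.177 with an estimated correlation. Of 33 genes of oxidative phosphorylation, 29 were negative by small amounts (median -0.06, adjusted p = 9.93e-05, or 0.298 with an estimated correlation). The remaining 12 called lists had medians within 0.24 of 0, and none held with an estimated correlation (adjusted p between 0.137 and 0.366). Of these, 9 were lost without 1 or more of the 8 arrays compared, with adjusted p up to 0.298 for the circadian clock without APP_KO array 3. The ER stress and heat shock call was lost without APP_KO array 2 (0.105), N_dCKO array 1 (0.0698) or N_dCKO array 2 (0.0698). Without N_dCKO array 1, 10 lists were called in place of 16. With the Gapdh ratio as a covariate 7 were called, oxidative phosphorylation among those lost (0.203).

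The interaction asks whether the effect of losing both genes departs from the sum of the single losses. The series title calls N_dCKO conditional, and how its alleles and breeding compare with those of the single knockouts is not given in the sources used here, so this test and each comparison of N_dCKO can hold differences other than the loss of APP and APLP2. No gene passed limma's test; 484 had an unadjusted p below 0.05, where chance gives 583, the smallest adjusted p was 0.557, and the 11 genes called without N_dCKO array 3 were the most of any fit with 1 array left out. The 5 genes with the smallest p were Galc (-0.70 ± 0.13), Gfpt1 (0.32), Cyb5d2 (-0.76), Cln8 (-0.60) and Slc32a1 (0.42). Lists moved more: all 18 choroid plexus genes were negative with a median of -1.23 (adjusted p = 7.32e-22), and 13 were lower over the list alone, such as Clic6 (-2.56 ± 0.78). All 11 genes of leptomeninges and fibroblasts were negative (median -0.40, adjusted p = 2.78e-07). Neither list was called with an estimated correlation (adjusted p = 0.224 for both), nor was any of the other 9 (0.224 to 0.633). Of the 9, ribosomal proteins (median -0.11) kept the call whichever array was left out but not with quantile normalization (0.243) or the choroid plexus covariate (0.0897), and each of the 16 arrays ended the call of 1 or more of the others, with adjusted p up to 0.497 for endothelium and mural cells without APLP2_KO array 4. The number of called lists was 6 without APP_KO array 4, 5 without APLP2_KO array 4 and 7 without N_dCKO array 4, against 11 with all arrays.

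No gene was called in the same direction in all 3 knockout groups against WT by limma, since APP_KO had App alone. Across 11662 genes, leaving out App and Aplp2, the log2 fold changes of APP_KO and APLP2_KO correlated at 0.43, those of APP_KO and N_dCKO at 0.49, and those of APLP2_KO and N_dCKO at 0.57, where genes are not independent replicates. Unchanged groups against the same WT arrays gave 0.50 in simulation. The covariances were 0.00878, 0.0137 and 0.0179, against simulated values of 0.00883, 0.00883 and 0.00882, which puts the covariances 0.00491 and 0.00908 above the simulated value for the last 2 pairs. The simulation takes arrays as independent, while WT and APP_KO arrays of the same number deviated together, which lowers the value without change for the pairs with APP_KO, so a shared effect of the first pair is not ruled out. Same-numbered APLP2_KO and N_dCKO arrays deviated together too, at 0.08 to 0.21. This raises the value without change for their pair, so part of its excess may come from it. The simulated shared calls given below leave it out as well. With the WT arrays split between the comparisons, the mean correlations were 0.03, 0.15 and 0.25. The split does not remove the shared deviations of same-numbered APLP2_KO and N_dCKO arrays. APLP2_KO and N_dCKO shared 9 called genes, 5 higher and 4 lower, where independent lists, a value that leaves out the shared WT arrays, would share 0.017 and 0.047, and unchanged groups against those arrays shared 0 in each of 100 simulations: Fxyd2, 2900052N01Rik, Galc, Trub2 and Ift46 were higher, and Pdgfd, Mpeg1, Ddx6 and Coro2b lower. In comparisons that share no array, APLP2_KO against WT and N_dCKO against APP_KO, 14 of the 14 genes called in the first had the same sign in the second, and 7 were called in both.

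Genes near the targeted genes were then examined, with positions from the GRCm38.p6 table used only for neighbourhood. None of the 89 tested genes within 10 Mb of Aplp2 was called in any comparison of 2 groups (Fisher's exact p = 1, two-sided). Within 20 Mb, 5 of 203 genes were called in APLP2_KO against WT (odds ratio 32.0, Fisher's exact p = 2.73e-06), 6 in N_dCKO against WT (3.38, p = 0.0116) and 3 in N_dCKO against APP_KO (4.61, p = 0.0323). Within 10 Mb of App, Clic6 and Kcne2 of 61 genes were called in N_dCKO against WT (Fisher's exact p = 0.11, adjusted 0.55) and in N_dCKO against APP_KO (0.0186, adjusted 0.186). Over the whole of chromosome 9, which like the 20 Mb window was an alternative fixed before the data were examined, calls were more frequent than elsewhere: 8 of 672 genes in APLP2_KO against WT (odds ratio 21.9, Fisher's exact p = 2.64e-07), 21 in N_dCKO against WT (4.03, 7.75e-07) and 10 in N_dCKO against APP_KO (5.50, 6.8e-05), Aplp2 left out.

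**Figure D4:**
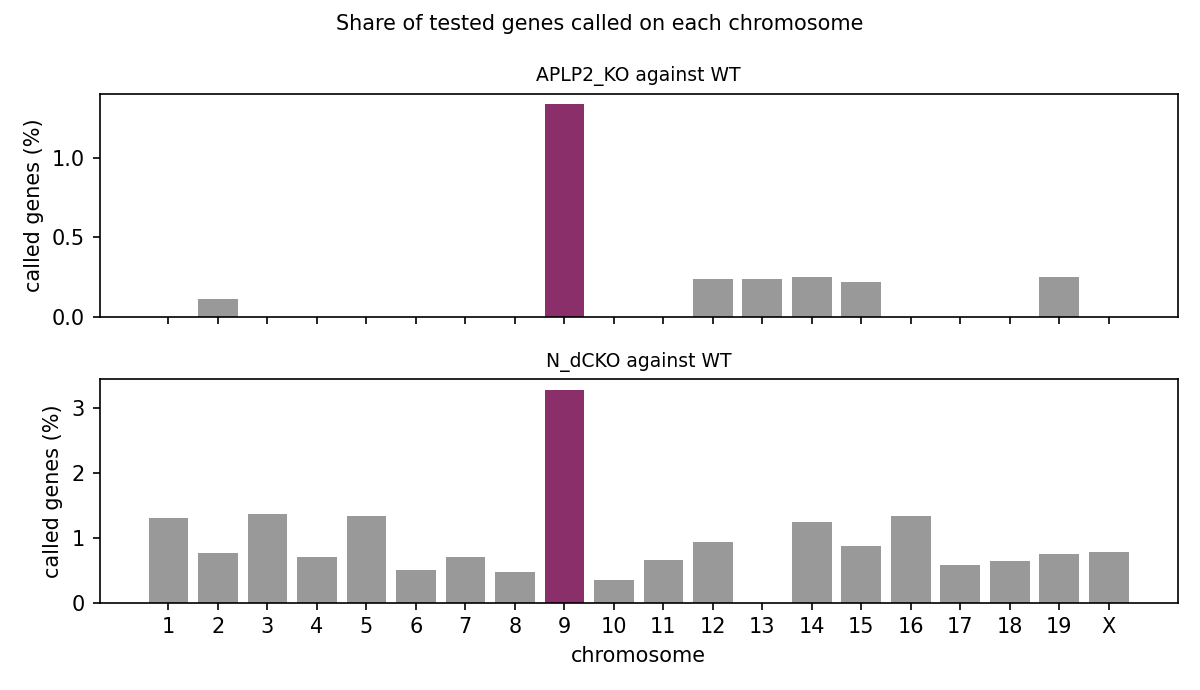
Percent of the tested genes of each chromosome that were called, for APLP2_KO against WT and for N_dCKO against WT. Chromosome 9, with Aplp2 included, holds 9 called genes of 673 in the first comparison and 22 in the second.

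Several lists were called in no comparison: CA2 and CA3 pyramidal neurons, thalamus and habenula, striatum, neocortex, postsynaptic scaffold, metal handling and promoters used in neuronal Cre lines. The lists of blood genes and of sex-linked genes for checking the labels had 1 and 3 tested members and were not tested as lists. In every called list the median, the mean and the test had the same sign.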

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

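The counts of other splits of the arrays were fixed before the data were examined. So were the permutation test of App, the list tests of the interaction, the test of each probe set, and the windows on chromosome 9. The use of these windows to weigh explanations, and all other tests in this part, were chosen after the results they concern had been seen. The microglia test without WT arrays replaced an earlier one. The chromosome 9 explanation by strain DNA was divided into a near and a distant part after a first run.

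The choroid plexus genes were low on 3 of 4 N_dCKO arrays, with a median log2 fold change of -1.96 against WT. An effect confined to the few genes described as responding to APP is argued against, since 12 of the 15 other members of the list were called lower (median -1.89). Whether those few genes carry an effect of their own was not tested. Less choroid plexus tissue in the samples is a candidate explanation. The 37 genes outside the list that follow it in the other 12 arrays had a median of -0.36. Of these, 33 were negative and 9 were called lower. They were chosen because they follow the list, so they would move with it under other causes too, and this test cannot part them. Whether the genotype lowers this tissue in every animal cannot be told apart from dissection, because 3 N_dCKO arrays lay below the other 12 and the remaining one did not. The labels do not say how the tissue was cut.

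Calls were concentrated on chromosome 9 in both groups without APLP2. DNA of another strain elsewhere on the chromosome, carried along with the targeted allele, may account for this: the odds ratio was 5.50 in N_dCKO against APP_KO, which shares no array with APLP2_KO against WT. Within 10 Mb of Aplp2, 0 genes were called where the rate of the chromosome predicts 1.06 and 2.78, too few to decide, while within 20 Mb 5 and 6 genes were called. Sequence differences under single probe sets stay open for part of the genes: 4 of 12 other probe sets (33.3%), of Fxyd2, 2900052N01Rik and Neo1, had the same sign with an unadjusted p below 0.05 in the average over mice without APLP2 against mice with it (8 against 8 arrays), while those of Ddx6 (0.15 and -0.17 against -0.58), Coro2b (-0.07 against -0.63) and Ccdc12 (-0.17 and -0.01 against -0.21) missed that threshold and 1 of 3 of Tmem30a passed it with the other sign (0.13 against -0.33). An effect of APLP2 loss itself cannot be told apart from linked DNA, since all 8 chromosome 9 genes called in APLP2_KO kept their sign in N_dCKO against APP_KO, which both predict.

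Microglia genes were lower in all 3 knockout groups, which share the WT arrays. For N_dCKO, high WT arrays are argued against: with no WT array, the list mean was 9.04 to 9.23 on N_dCKO arrays and 9.25 to 9.41 on those of the single knockouts (exact two-sided permutation p = 0.00202, 4 against 8 arrays), while the first version of this test, camera with an estimated correlation in N_dCKO against APP_KO, gave adjusted p = 0.0458, or 0.0692 without the variance trend. For APP_KO and APLP2_KO no comparison without WT arrays exists, and the APP_KO call is lost with an estimated correlation (adjusted p = 0.0538). Macrophages lost with the choroid plexus are argued against, as the slope within the other 12 arrays predicts a change of -0.05 ± 0.10, against -0.37 ± 0.05 seen. For RNA quality, the slope on the Gapdh ratio within groups over 16 arrays predicts -0.03 ± 0.04. That slope was uncertain (-0.283 ± 0.422), and the ratio does not overlap between WT and N_dCKO. The list kept its camera call with the ratio as a covariate, but RNA quality cannot be told apart from the genotype here. A lower share of microglia RNA and lower expression in each cell both stay open, untested.

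Among the 35 splits of the arrays, the real one alone gave as many calls in 3 comparisons. These were APLP2_KO against WT (15, highest other 1), N_dCKO against WT (110, highest other 0) and N_dCKO against APP_KO (41, highest other 24, with N_dCKO array 3 in exchange for APP_KO array 1). A share of 1 in 35 is the smallest this test can give. It was not adjusted over the comparisons, and the real counts include App or Aplp2. The splits thus argue against chance but do not exclude it. The 1 call of APP_KO against WT is App, the gene that the group is labelled as lacking (-2.88 ± 0.07, limma adjusted p = 2.56e-16). Its exact permutation p of 0.0286 is the smallest possible. The arrays did not overlap for 2.63% of all tested genes, so that p alone does not exclude chance. The number of calls alone would not exclude chance there, since 7 of 35 splits gave 1 call or more and 1 of them gave 20, with APP_KO array 2 in exchange for WT array 4, which points to a structure of the samples. Of the 8 splits that part every same-numbered pair of WT and APP_KO arrays, 1 gave as many, the real one, and the highest other gave 0. In N_dCKO against APLP2_KO, 5 of 35 splits gave at least its 3 calls (highest other 5). Of the 8 splits that part every same-numbered pair of these arrays, the real one alone gave as many, and the highest other gave 0. A share of 1 in 8 is the smallest these splits can give, so chance stays open for Defb11 and Cldn2. The remaining call is App, which the N_dCKO label gives as lost (-3.16 ± 0.07, limma adjusted p = 4.18e-17). Its exact permutation p of 0.0286 is again the smallest possible. For the interaction the count decides nothing, since with 0 real calls each of the 100 splits drawn gives as many; the highest other split gave 45, which points to a structure of the samples too.

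Single arrays stood apart from the other 3 of their group in 29 of 504 groups of values tested, by the gap to the nearest array divided by the range of the group (Dixon's ratio above its 95% critical value for 4 arrays), where chance gives about 1 in 20 groups, or 25.2. High on 1 array, with its ratio, were Aplp1 in APP_KO array 3 (0.892), Crh in APLP2_KO array 2 (0.835), Fxyd2 in APLP2_KO array 2 (0.833), Gfpt1 in WT array 2 (0.857), Hcrt in APLP2_KO array 1 (0.947), Htr3a in WT array 1 (0.931), Selplg in APLP2_KO array 3 (0.904), Tdo2 in APLP2_KO array 1 (0.866), Tenm3 in WT array 4 (0.901) and N_dCKO array 1 (0.907), and Zbtb16 in WT array 1 (0.881) and APP_KO array 1 (0.933). N_dCKO array 3 was high for Cldn2 (0.832), Folr1 (0.875), Kcne2 (0.855) and Krt18 (0.868) and low for Dcn (0.931) and Tyrobp (0.942). Low on 1 array were Ccdc153 in APP_KO array 1 (0.942), Col19a1 in N_dCKO array 4 (0.901), Folr1 in APLP2_KO array 4 (0.939) and Zfp874a in APLP2_KO array 1 (0.89). Among list means, calcium channels, stores and pumps were high in APLP2_KO array 4 (0.841), and low were ependyma in APP_KO array 1 (0.84), GABAergic interneurons in WT array 2 (0.911), CA1 pyramidal neurons in APLP2_KO array 1 (0.854), sodium and potassium channels in N_dCKO array 4 (0.831), adhesion and axon guidance in WT array 2 (0.854) and oxidative phosphorylation in N_dCKO array 4 (0.849).

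The interaction test called 11 lists by camera and none with an estimated correlation. The adjusted p was 7.32e-22 for choroid plexus, 2.78e-07 for leptomeninges and fibroblasts, 4.35e-05 for ribosomal proteins, 0.00287 for oxidative phosphorylation, 0.0184 for GABAergic interneurons, 0.0186 for oligodendrocyte precursors, 0.025 for circadian clock, 0.0272 for insulin and IGF signalling, 0.0357 for immune activation and antigen presentation, 0.0481 for endothelium and mural cells and 0.0493 for genes described as responding to APP or its fragments.

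Of 1942 tested probe sets that the annotation used here does not name, 1 was called in APP_KO against WT, 2 in APLP2_KO against WT, 16 in N_dCKO against WT (8 higher and 8 lower), 1 in N_dCKO against APLP2_KO and 2 in N_dCKO against APP_KO.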

How the results depend on the processing

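The fits with the choroid plexus covariate and with the Gapdh ratio covariate, the one without the genes that follow it, the one of the compared groups with a block, and camera without the variance trend were chosen after seeing the data. With 4 arrays per group the number of arrays limits the precision, and genes of low signal lie near background. The median log2 fold change over all genes stayed within 0.016 of 0 in every comparison under each alternative scaling and filter.

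App and Aplp2, in the comparisons where their group lacks them, kept direction in every fit and the call in all but 1: Aplp2 in APLP2_KO against WT (-2.39) was not called by the ordinary test, which estimates each gene's spread from 8 arrays alone. Over fits without 1 array, App lay between -2.92 and -2.84 in APP_KO and between -3.12 and -3.02 in N_dCKO against WT, and between -3.21 and -3.11 in N_dCKO against APLP2_KO. Aplp2 lay between -2.52 and -2.24 in APLP2_KO and between -2.64 and -2.51 in N_dCKO against WT, and between -2.59 and -2.46 in N_dCKO against APP_KO. The counts of genes ranged from 1 to 16 (APP_KO against WT), 9 to 18 (APLP2_KO against WT), 45 to 115 (N_dCKO against WT), 1 to 35 (N_dCKO against APLP2_KO), 19 to 56 (N_dCKO against APP_KO) and 0 to 11 (interaction), and those of lists from 8 to 14, 7 to 14, 21 to 24, 15 to 19, 10 to 17 and 5 to 11 in the same order.

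Other counts of genes moved as follows, and except where a reason is given the cause was not tested. In APP_KO against WT, 3 probe sets were called one by one and 6 genes with only the groups compared and a block. In APLP2_KO against WT the count was 3 with the 75th percentile filter, 33 for single probe sets, 30 with the replicate block, 37 with only the groups compared and the block, and 0 by the ordinary test. In N_dCKO against WT it was 60 with that filter, 73 without the intensity trend, 170 with array weights, 198 with the replicate block, 5 by the ordinary test, 3 with the choroid plexus covariate and 63 without the genes that follow it. In N_dCKO against APLP2_KO it was 5 with 4 times the pseudocount, 1 without a filter, with the 75th percentile filter, without the trend, by the ordinary test and without choroid-following genes, 6 for single probe sets, 30 with array weights, 17 with the block and 55 with only the groups compared and the block. In N_dCKO against APP_KO it was 15 with the filter, 20 without the trend, 2 by the ordinary test, 9 with only the groups compared, 1 with the covariate and 20 without choroid-following genes. With the Gapdh ratio covariate it was 8 and 23 in APLP2_KO and N_dCKO against WT, and 1 and 20 in N_dCKO against APLP2_KO and APP_KO. The stricter filter tests fewer genes, the choroid plexus covariate is confounded with the group, and the Gapdh ratio does not overlap between WT and N_dCKO.

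Lists called in APP_KO against WT were 7 with quantile normalization, 5 without a filter and 0 with an estimated correlation, with or without the trend. With an estimated correlation the other counts were 1 (APLP2_KO against WT), 4 (N_dCKO against WT), 1 (N_dCKO against APLP2_KO), 2 (N_dCKO against APP_KO) and 0 (interaction), and without the trend as well 1, 1, 1, 0 and 0. The interaction gave 7 without a filter and 7 in camera without the trend, and N_dCKO against APP_KO gave 7 with the Gapdh ratio covariate. At the preset correlation, leaving out the trend ended the interaction calls of immune activation and antigen presentation, endothelium and mural cells, insulin and IGF signalling, and genes described as responding to APP or its fragments. It also ended the calls of dentate granule neurons, oxidative phosphorylation and ribosomal proteins in APP_KO against WT, and of the circadian clock in N_dCKO against WT. In N_dCKO against APLP2_KO it ended that of sodium and potassium channels. In N_dCKO against APP_KO it ended those of glutamate receptors, GABA receptors and genes described as responding to APP or its fragments. Quantile normalization ended the calls of ribosomal proteins in APP_KO against WT, N_dCKO against APLP2_KO and the interaction, of immune activation and antigen presentation in the last 2, and of dentate granule neurons, oxidative phosphorylation and neuropeptides in APP_KO against WT. With the choroid plexus covariate 3, 8, 3 and 3 were called in N_dCKO against WT, APLP2_KO and APP_KO and in the interaction.

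With the choroid plexus covariate, directions turned for Kcne2 (0.08 against WT) and Otx2 (0.13 against WT and 0.04 against APP_KO). The fitted value of Ttr there (0.44) comes from a probe set near the ceiling of the array, and neither a size nor a direction is read from it. With this covariate lists turned too, at adjusted p of 0.515, 0.315 and 0.278 for ependyma in N_dCKO against WT, APLP2_KO and APP_KO, 0.846, 0.902 and 0.706 for choroid plexus in N_dCKO against APLP2_KO and APP_KO and in the interaction, and 0.712 for ER stress and heat shock against APP_KO. Oxidative phosphorylation turned in the interaction with quantile normalization (0.909), and immediate early genes in APP_KO against WT without APP_KO array 2 (0.917, with adjusted p from 3.41e-06 over the fits without 1 array). Of 1830 alternative values of 79 called gene and comparison pairs, 4 turned, that of Ttr included, 501 lost the call and 1325 kept it, and 89 of 8353 values of pairs not called passed the threshold. With the WT arrays split, the correlations of fold changes were 0.03, 0.15 and 0.25. Calls near Aplp2 were 5, 6 and 3 within 20 Mb and 8, 21 and 10 on the whole chromosome (APLP2_KO and N_dCKO against WT, N_dCKO against APP_KO).

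With the replicate block, lists gained a call in APLP2_KO against WT (interferon response 0.0449, adhesion and axon guidance 0.0449), N_dCKO against WT (postsynaptic scaffold 0.0392) and N_dCKO against APP_KO (oligodendrocytes and myelin 0.0427, immediate early genes 0.0419), and lost it in N_dCKO against APLP2_KO (sodium and potassium channels 0.0561) and the interaction (genes described as responding to APP or its fragments 0.068). The block changed no other list call, and none in APP_KO against WT. Outside WT and APP_KO, APLP2_KO and N_dCKO arrays of the same number correlated at 0.08 to 0.21 in their deviations, with 8 of 8 arrays best with their own number, which is a hint from the data, and other pairs of groups at -0.02 to 0.11.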

Other observations

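The comparisons over 8 against 8 arrays in this part, and the tests of App and of myelin genes, were all chosen after the results had been seen.

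When mice without APLP2 were set against mice with it, averaged over the state of App, limma called 107 genes, 35 higher and 72 lower, of which 35 lie on chromosome 9, Aplp2 included. Of the 107, 14 are on the choroid plexus list or follow it in the 12 arrays outside N_dCKO, such as Defb11 (-1.84 ± 0.31) and Aqp1 (-1.52 ± 0.27), and all 14 were lower. The group means of Defb11 were 8.65 in WT, 7.93 in APP_KO, 7.80 in APLP2_KO and 5.10 in N_dCKO, so that the low N_dCKO arrays enter these calls. The genes named here lie on other chromosomes than 9 and were chosen after their values were seen. Cetn4 and Exosc9 share chromosome 3, where linked DNA of another strain was not tested. Trub2 was higher by 0.59 ± 0.07 (limma adjusted p = 0.000191) and Mpeg1 fell by 0.99 ± 0.10 (1.44e-05), and both were called in APLP2_KO against WT and in N_dCKO against APP_KO, which share no array. In this average Card10 was higher by 1.05 ± 0.13 (0.00021), Cetn4 fell by 1.13 ± 0.15 (0.000496), Exosc9, a part of the RNA exosome, fell by 0.97 ± 0.13 (0.000333), and Selplg, a selectin ligand of leukocytes and microglia, fell by 0.42 ± 0.06 (0.00171). None of these 4 was called in APLP2_KO against WT (adjusted p = 0.052 for Card10, 0.111 for Cetn4, 0.052 for Exosc9 and 0.0537 for Selplg). Wdfy1 passed in the average too (1.16 ± 0.18, 0.00171), but its WT arrays lay at separate levels. Relative to their mean, WT arrays 1 and 4 read 0.71 and 0.65, within the 0.56 to 1.30 of the groups without APLP2, and WT arrays 2 and 3 read -0.79 and -0.58, within the -1.02 to -0.57 of APP_KO, which goes against a rise from the loss of APLP2 alone.

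The corresponding comparison for APP called App and Mag (-0.52, adjusted p = 0.0475). With an estimated correlation, the microglia list was lower in mice without APP (16 of 16 genes negative, median -0.17, adjusted p = 0.0171) and in mice without APLP2 (16 of 16, median -0.17, 0.0111). GABAergic interneuron genes were higher in mice without APP (14 of 14 positive, median 0.09, 0.0171), but camera did not call this list in APP_KO against WT (adjusted p = 0.123) and called its interaction (0.0184, or 0.224 with an estimated correlation), so the average does not describe APP_KO. Genes of cholesterol and fatty acid synthesis were lower (18 of 19 negative, median -0.17, 0.0212). The same arrays enter both comparisons of microglia genes, and the differences between them were not tested.

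A lower share of oligodendrocyte RNA in both groups without APP may underlie the myelin values (16 of 16 genes negative, median -0.39), but the list missed the threshold with an estimated correlation (adjusted p = 0.063), which leaves this open.

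The title names a neuronal knockout, so cells other than neurons might keep App in N_dCKO. The data argue against a remainder above 10% of WT on 1 App probe set. There the N_dCKO arrays read 5.13%, 4.87%, 6.16% and 5.18% of the WT mean, and the group means were 5.34% in N_dCKO and 5.76% in APP_KO. The brightest App probe set read 11.8% in N_dCKO and 13.6% in APP_KO. On neither did N_dCKO keep more App signal than APP_KO. How much App signal cells other than neurons give in WT is not known here, so a smaller remainder is not excluded.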
